A study of Mus musculus with 289 samples.

How the data were processed

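The samples were single astrocytes drawn from the cortex of adult Cas9-expressing mice with an electrophysiology pipette, and each was made into a Smart-seq2 library, which has no molecular identifiers. The mice had received a lentivirus made to act in astrocytes, carrying guide RNAs (gRNAs) against Sox9, Trps1 or both, or a control gRNA. Cells with no gRNA and in-slice controls, in which the pipette entered the slice and took no cell, were labelled as well. Whether the animals of no gRNA cells received a virus is not given in the sources used here. The labels gave 289 samples in 5 batches. Of these, 254 had a column of values (242 astrocytes and 12 in-slice controls), and 35 samples of batch 4 had none and were not analysed here. Those 35 were all 12 Trps1 gRNA cells of day 21, 16 of the 31 Trps1 gRNA cells of day 7, 4 Sox9 gRNA cells, 2 control gRNA cells and 1 cell with both gRNAs.

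The values were raw counts of reads per gene and cell, deposited by the authors in 1 table per batch. They were whole numbers whose totals differed between cells, and no normalization was seen in them. STAR 2.6.0a, RSEM 1.3.0, GRCm38 and mm10 are named per the submitters' processing notes, with no role given. How strand and gene filters were handled is not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies such as the alpha and beta globin pairs could not be separated. Rows that name no gene were kept out of all totals. They held 75.6% of counts in batch 1 (unassigned reads) and 22.3% in batch 2 (spike-ins), and under 1% in the other batches (vector, reporter and guide sequences). Gene IDs were matched to symbols from the supplied name table: 55141 of 55487 gene rows in batch 1, 23747 of 23787 in batch 2, 24265 of 24304 in batch 3, 34531 of 34636 in batch 4 and 27786 of 27849 in batch 5. Coordinates are GRCm38, from the GENCODE annotation supplied with the files.

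Astrocyte totals ran from 15959 to 4656612 reads in genes (median 1094502), with a median of 4223 genes with a read (826 to 12740). In-slice controls held 341394 to 2299609 reads and a median of 2937 genes.

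The labels name no animal, so cells could not be assigned to animals and cells are not replicates. Each gRNA group, day and batch was treated as 1 pool, and no test, p-value or standard error was computed for any comparison. For each pool the counts were summed and given as CPM, the gene's share of all reads in genes on the usual scale, with an exact Poisson interval. The share of cells with at least 1 read was given with an exact binomial (Clopper-Pearson) interval. Both intervals are at 95% and cover counting error only. They leave out the variation between cells and between animals. Where a pool held no read, the limit is set by 3 counts. A log2 ratio compares the pools' CPM after adding 5 to each, which draws ratios of low genes towards 0, so it is no bound where a pool is at 0. Comparisons stayed within a batch.

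Genes were named by a rule fixed before the data were examined. A gene needed 20 CPM or more in the higher pool, a read in 40% or more of its cells, and a share of cells differing by 20 percentage points or more. It also needed a log2 ratio of at least 1 in the same direction after the highest cell of each pool was left out, and the same direction in a second batch holding the same groups. The highest cell is that for the gene in question, so the cells left out differ between genes. Genes were ranked by that last ratio: 10 each way against a control or no gRNA reference, and 5 each way elsewhere. Genes of uncertain name, mitochondrial and ribosomal protein genes were not named, and some genes that met the rule are not reported here. Sox9 and Trps1 were reported whatever their values, with up to 4 members of each list picked for naming.

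The lists, also fixed beforehand, were 16 gene lists and 9 marker lists of cell types. The gene lists covered the targets and related transcription factors, astrocyte identity, reactive astrocytes, the interferon and antiviral response, the p53 response, the cell cycle, and glutamate, GABA and ion handling. They also covered astrocyte factors acting on synapses, cholesterol and fatty acid synthesis, the circadian clock, extracellular matrix and cartilage, and Notch, BMP, Wnt, FGF and hedgehog signalling. The last were immediate early and stress genes, glycolysis and lactate, oxidative phosphorylation, and neurogenic and neuronal progenitor genes. The marker lists were excitatory, inhibitory and pan-neuronal genes, oligodendrocytes, their progenitors, microglia and macrophages, endothelium, pericytes with smooth muscle and fibroblasts, and ependyma. A list's shift is its median log2 ratio minus the median of 10000 random lists of the same size matched on mean expression in 20 bins, over genes at 5 CPM or more. A list is higher or lower relative to matched genes, so where most genes move its own CPM need not change: over all genes at that minimum the median log2 ratio ran from -0.59 to 1.43 between comparisons. A list was called outside chance lists beyond percentiles 2.5 and 97.5. The percentile describes these libraries and is not a test between conditions.

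The naming rule was tested on simulated data drawn from real cells, with 200 genes altered by known folds in 20 draws. Both pools were drawn from the cells of the reference pool, so differences between the real groups did not enter. Lists of 25 unaltered genes picked at random were ranked in the same draws. In groups of the size of the Sox9 against control comparison, a median of 8.53% of 5174 unaltered genes passed the naming rule (1.02% to 26.4% over draws). Genes altered 8-fold in amount passed in 15.2% and those altered 8-fold in their share of cells in 51.5%. A median of 6.0% of 50 random lists fell outside the percentiles. For the day 7 dual gRNA comparison with 6 reference cells, the passing share of 3502 unaltered genes reached 54.4% in single draws. The share of random lists outside the percentiles reached 58.0%. Random lists are not made of genes that move together, and the fixed lists were not run. These shares are therefore no error rate for the fixed lists. Named genes therefore describe these cells, and chance picks are expected among them.

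Columns were compared for duplicates. No pair was identical. A chi-square per gene over genes with 20 or more reads found 2 pairs far below all others, under a threshold of 10 that, like a minimum depth of 100000 reads, was chosen after seeing the data. Alternatives covered the weight and scale of cells, the highest cell, cell quality (1000 genes and 50000 counts), TMM factors, thinning to 100000 reads, the prior (1 and 20 CPM), list minimums, title series, and genes of the in-slice controls. Leaving out mitochondrial genes, counting a near-identical pair as 1 cell, batch 2 lists without the highest cells, in-slice sums without the highest library, and a comparison of Trps1 gRNA day 7 with control gRNA day 21 cells were added after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and edgeR 4.0.16 in R 4.3.3 for TMM factors alone.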

Results

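Single astrocytes of the adult mouse cortex were compared after gRNAs against the transcription factors Sox9 and Trps1 had been delivered to Cas9-expressing mice. Batch 1 held 31 cells with no gRNA, 10 with control gRNA and 4 with both targeting gRNAs. Batch 2 held 8 control gRNA cells of day 7, 7 of day 21 and 8 cells with both gRNAs of day 21. Batch 3 held 21 Sox9 gRNA cells and 14 cells with both gRNAs of day 7, with 6 no gRNA cells. Batch 4 held 15 control gRNA, 16 Sox9 gRNA and 13 dual gRNA cells of day 21, and 15 Trps1 gRNA cells of day 7. Batch 5 held 21 Sox9 gRNA and 30 Trps1 gRNA cells of day 21, with 23 no gRNA cells. Median totals per cell ran from 825683 reads in batch 5 to 2320950 in batch 2. In batch 1 the labels gave control cells days 8 to 16 and dual gRNA cells days 17 to 20, so day was not used there. Each pool of cells stands alone because the labels name no animal, so every difference describes these libraries and has no replicate check.

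Sox9 (ENSMUSG00000000567, GRCm38 chromosome 11, 112782224 to 112787760, plus strand), a transcription factor of the astrocyte and cartilage lineages, was not uniformly lower in cells labelled with its gRNA. In batch 4 it stood at 189 CPM (183 to 195) in Sox9 gRNA cells, 177 CPM (171 to 184) in control gRNA cells and 133 CPM (127 to 138) in dual gRNA cells. In batch 5 it stood at 233 CPM (226 to 240) in Sox9 gRNA, 664 CPM (655 to 674) in Trps1 gRNA and 309 CPM (300.4 to 317) in no gRNA cells. In batch 3 it was higher in both gRNA pools, at 1303 CPM with Sox9 gRNA and 1492 CPM with both gRNAs against 382 CPM with no gRNA. The log2 ratio was 0.11 with title series 7S of the Sox9 gRNA cells alone and 0.12 with series 7ST of the dual gRNA cells alone. On mean log2 values that of dual gRNA cells turned to -0.11. In batch 2 the dual gRNA pool held 905 CPM and the control pools 491 CPM at day 21 and 413 CPM at day 7. Trps1 gRNA cells of day 7 in batch 4 held 52.5 CPM. In batch 1 the levels were 1860 CPM with both gRNAs, 209 CPM with control gRNA and 524 CPM with no gRNA.

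Trps1 (ENSMUSG00000038679, chromosome 15, 50654752 to 50890463, minus strand), a GATA-type zinc finger repressor, was lower in dual gRNA cells of batch 2 (19.4 CPM, 17.5 to 21.3) than in control gRNA cells of day 21 (107 CPM, 102 to 112) and of day 7 (174 CPM). The day 21 values were 0.173 and 62.8 CPM without the highest cells. In batch 5 it stood at 57.6 CPM in Trps1 gRNA, 39.7 CPM in Sox9 gRNA and 91.9 CPM in no gRNA cells (23.5, 17.1 and 59.96 CPM without the highest cells). Against series 2AG of the no gRNA cells alone, the log2 ratios in Trps1 and Sox9 gRNA cells turned to 0.75 and 0.26, and with series 21T2 alone that of Trps1 gRNA cells to 0.41. Trps1 was higher in dual gRNA than in control gRNA cells of batch 4, at 16.7 against 3.35 CPM (2.43 against 2.07 CPM without the highest cells), and stood at 41.4 CPM in Sox9 gRNA cells there. In batch 3 it stood at 294 CPM in dual gRNA, 74.0 CPM in Sox9 gRNA and 109 CPM in no gRNA cells. Without the highest cells these were 92.5, 54.7 and 8.79 CPM, so the order of Sox9 gRNA and no gRNA cells turned. In batch 1 it was lower in control gRNA (4.61 CPM, 3 of 10 cells) than in no gRNA cells (96.1 CPM, 16 of 31), with 112 CPM in dual gRNA cells. Trps1 gRNA cells of day 7 held 102.7 CPM. Single cells carried several of these sums. Without its highest cell, the dual gRNA pool of batch 3 dropped to 390 CPM of Sox9, that of batch 4 to 23.4 CPM of Sox9, and the Trps1 gRNA day 7 pool to 9.21 CPM of Trps1. Pools of in-slice controls held Sox9 at 0.166 CPM or less and Trps1 at 3.49 CPM or less, with single libraries at up to 0.463 and 10.8 CPM, and a pool without a read allows up to 1.88 CPM. Changes that Cas9 makes in a gene need not lower its mRNA, so these levels neither bear out nor contradict the labels. Groups below are the cells labelled with each gRNA. Guide sequences were counted in batches 2 and 3. In batch 2 the Sox9 guides were read in 3 and 1 of 8 dual gRNA cells and in none of the 7 and 8 control gRNA cells. In batch 3 a Sox9 guide, the first of the pair, was read in 12 of 14 dual gRNA and 13 of 21 Sox9 gRNA cells. The other was read in 3 and 16 cells. The Trps1 guide was read in 9 of 14 dual gRNA cells, but also in 4 of 21 Sox9 gRNA cells. No guide was read in the 6 no gRNA cells, which allows a share of cells up to 45.9%. Those cells were shallow, with a median of 236508 reads.

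**Figure D1:**
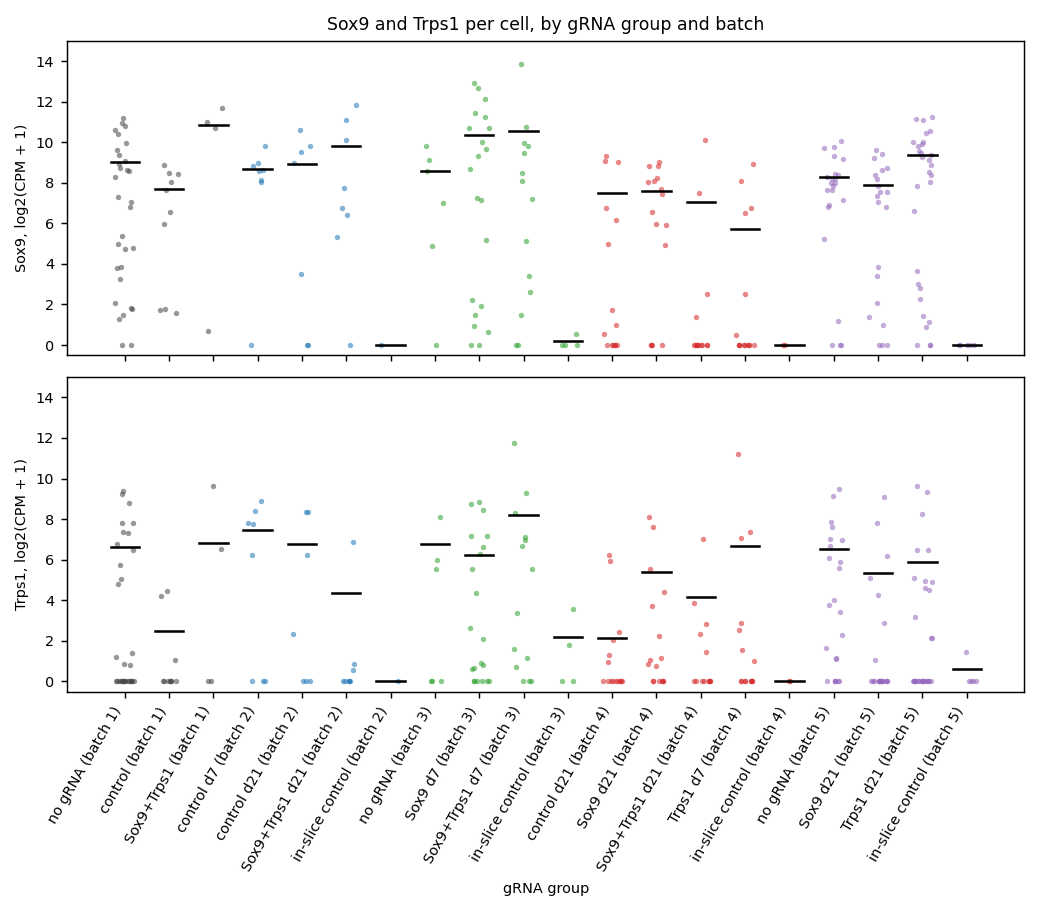
Sox9 (upper) and Trps1 (lower) per cell as log2(CPM + 1), by gRNA group and batch. Each point is 1 cell, the line is the pool's CPM on the same scale, and colours mark batches. The dual gRNA pool of batch 3 (1492 CPM of Sox9) rests on a cell at 14893 CPM.

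Cells labelled with Sox9 gRNA were set against control gRNA cells at day 21 in batch 4, which asks what targeting Sox9 does in an adult astrocyte. Higher in the Sox9 gRNA libraries were Mlc1, a membrane protein of astrocyte endfeet (399 against 49 CPM, 14 of 16 against 6 of 15 cells), Slc4a4, a sodium bicarbonate cotransporter (219 against 37.8 CPM), and Fgfr3, a growth factor receptor (385 against 100.2 CPM). Haemoglobin chains were higher too, with Hbb-bs at 5425 against 30.5 CPM, Hba-a1 at 2077 against 5.44, Hba-a2 at 1097 against 0.825 and Hbb-bt at 962 against 2.86, alongside Alas2, the erythroid enzyme that starts haem synthesis (154 against 2.42 CPM). Col1a1, a fibrillar collagen chain, Spp1, the secreted phosphoprotein osteopontin, Ivd, an enzyme of leucine breakdown, and Phkg1, a subunit of phosphorylase kinase, completed the higher genes, with log2 ratios of 4.67, 5.78, 4.26 and 4.34. Lower were H2-DMa, which loads peptides on MHC class II (21.7 against 497 CPM, 2 of 16 against 12 of 15 cells), the lysosomal protease Ctsc (30.5 against 400.3 CPM), Cd83, a surface protein of activated immune cells (31.2 against 614 CPM), and Unc93b1, which carries Toll-like receptors to endosomes (22.1 against 349 CPM). Bin2, Cmtm6, Prkcd, Psme2 and Surf4 were lower with log2 ratios from -3.98 to -3.39.

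The astrocyte identity list shifted by 0.72 (percentile 99.6 of matched lists) and glutamate, GABA and ion handling by 0.78 (98.2). These shifts are relative to other genes, whose median log2 ratio was -0.59, and summed identity genes stood at 31466 against 31184 CPM. The reactive astrocyte list shifted by -0.91 (0.13), with the transcription factor Stat3 at 16.2 against 148 CPM and S100a10 at 0 against 29.6 CPM. Oligodendrocyte markers shifted by -2.09 (0), with the myelin genes Mal at 0.114 against 414 CPM and Cldn11 at 0.229 against 125 CPM, each read in 5 or fewer of the 15 control cells. Of 24 lists with a value, 20 lay within chance lists, among them the microglia and macrophage list (-0.34, 13.9), whose summed level was 7212 against 14553 CPM, and pericytes, smooth muscle and fibroblasts (1.83, 97.0). The oligodendrocyte call ended without the highest cells (-0.18). Mitochondrial genes took 5.43% of the Sox9 gRNA pool and 3.05% of the control pool. With only the cells of title series 21S, the identity shift (0.64 and inside chance lists without genes of the in-slice controls) turned to -0.13, ion handling to -0.15, Hbb-bs to -1.19, Alas2 to -0.078, Col1a1 to -0.51 and Spp1 to -0.11. Across 5636 genes, these log2 ratios had a Spearman correlation of -0.08 with those of Sox9 gRNA against no gRNA cells in batch 5, where the reference differs, and genes are not independent replicates.

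Cells labelled with both gRNAs were set against control gRNA cells of day 21 in batches 4 and 2. In batch 4 astrocyte genes were lower, with Gpr37l1, an astrocyte receptor, at 39.9 against 1118 CPM, Plpp3, a lipid phosphatase, at 30.5 against 616 CPM, and Mfge8, a bridging factor for phagocytosis, at 4.42 against 181 CPM. In batch 2 Plpp3 had a ratio of 0.23, and Mfge8 was higher in dual gRNA cells, at 462 against 0.402 CPM (7 of 8 against 1 of 7 cells). Lower in both batches were Slc27a1, a fatty acid transporter (-6.25 in batch 4 and -3.64 in batch 2), Gpam, which begins glycerolipid synthesis (-3.80 and -5.84), and Cyp2d22, a cytochrome P450 (-3.51 and -3.58). Egr2, an immediate early transcription factor (-5.67 and -2.33), Ccnd1, the D-type cyclin of the G1 phase (-3.60 and -2.03), Gstm5 (-3.28 and -1.85) and Scpep1 (-2.36 and -2.9) were lower as well. Higher in both batches were Akirin1 (2.88 and 3.65), Coprs (3.58 and 3.0), the proteasome subunit Psmd13 (2.44 and 2.85), Naxe (2.88 and 2.65), Tcirg1, a subunit of the vacuolar proton pump (2.75 and 2.54), Sra1 (3.16 and 1.89) and Epb41l2 (1.43 and 1.99). The histone variant H2afv, Mvb12a and Ninj1 were higher in batch 4 with batch 2 ratios of 0.25, 0.29 and 0.78, and Gpr37l1 and Rab18 were lower with batch 2 ratios of -0.06 and -0.02. As the rule asked for 1 direction in both batches, these shared directions are a choice and not a finding.

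In batch 4 the astrocyte identity list shifted by -1.64 (percentile 0), glutamate, GABA and ion handling by -0.996 (0.06), extracellular matrix and cartilage by -0.90 (0.05), Notch, BMP, Wnt, FGF and hedgehog signalling by -0.84 (0.22) and reactive astrocyte genes by -0.66 (0.69). Markers of other cell types moved with them: oligodendrocytes by -1.31 (0.22), endothelium by 2.31 (100), with the receptor Eng at 75.4 against 0.055 CPM, ependyma by 2.23 (98.8) on 3 members, and microglia and macrophages by 0.47 (97.7), with the surface phosphatase Ptprc at 185 against 5.003 CPM. Mitochondrial genes took 7.73% of the dual gRNA pool and 3.05% of the control pool. In batch 2 Eng and Ptprc had ratios of -0.86 and -2.40, the identity list shifted by 0.19 (75.5), and the called lists were others. Cell cycle genes shifted by 2.99 (99.98), with the replication clamp Pcna at 326 against 14.6 CPM, and the p53 response by 2.28 (99.02), with the cell cycle inhibitor Cdkn1a at 435 against 26.5 CPM. Oligodendrocyte progenitor genes shifted by -2.53 (0.19) and oxidative phosphorylation by -0.68 (1.06). Without the highest cells, which was run after seeing the data, none of these batch 2 calls stood: the cell cycle was at -0.040 (49.1, 7 members), the p53 response at 1.02 (79.6) and oxidative phosphorylation at -0.46 (7.12), with too few progenitor genes left. Over the 4567 genes in both batches the log2 ratios had a Spearman correlation of 0.01 across genes, and 50.8% had the same sign. Without the highest cells the oligodendrocyte shift of batch 4 was 0.060, and the calls of extracellular matrix (-0.43) and microglia (0.45) ended.

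Cells labelled with Sox9 gRNA at day 21 were set against no gRNA cells in batch 5. Genes of microglia and macrophages were higher in the Sox9 gRNA libraries, among them the complement genes C1qb (1548 against 20.8 CPM, 19 of 21 against 6 of 23 cells) and C1qc (906 against 5.39 CPM), Ctss, a lysosomal protease (2127 against 18.96 CPM), the fractalkine receptor Cx3cr1 (685 against 4.37 CPM), Lyz2 (647 against 0.341 CPM) and Laptm5 (756 against 10.4 CPM). The MHC class I chains H2-D1 (778 against 3.75 CPM) and H2-K1 (449 against 5.85 CPM), the actin regulator Arpc1b (427 against 1.02 CPM) and the immunoglobulin chain Ighm (394 against 0.057 CPM) were higher as well. Genes lower in the Sox9 gRNA cells were Dhcr7, an enzyme of cholesterol synthesis (34.01 against 397 CPM), Igfbp2 (49.8 against 448 CPM), Cmtm5 (39.2 against 248 CPM), Chil1 (19.5 against 182 CPM), the synapse factor Chrdl1 (17.03 against 122 CPM), Prelp, Ppp1r3g and Col16a1 (log2 ratios -3.48, -3.09 and -4.52). Cwc22 (ENSMUSG00000027014, chromosome 2, 77881159 to 77946375), a splicing factor, stood at 19.4 against 305 CPM, and Xist (ENSMUSG00000086503, chromosome X), the RNA of X inactivation, at 0.585 against 189 CPM.

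The microglia and macrophage list shifted by 4.38 (percentile 100), oligodendrocytes by 2.43 (100), reactive astrocyte genes by 2.2 (100), interferon and antiviral genes by 1.63 (100), cell cycle genes by 0.88 (97.505) and immediate early and stress genes by 0.56 (99.3). Lower were astrocyte identity (-0.32, 2.02), with Mfge8 at 700.0 against 3004 CPM and the coagulation factor receptor F3 at 222 against 1298 CPM, extracellular matrix (-1.12, 0), astrocyte factors acting on synapses (-0.66, 0.28), glutamate and ion handling (-0.56, 0.33), cholesterol and fatty acid synthesis (-0.45, 0.91) and oxidative phosphorylation (-0.41, 0.77). Inhibitory neuron (-1.51, 0.12), pan-neuron (-0.66, 0.29) and pericyte markers (-1.98, 0.05) were lower too. The no gRNA cells fell into title series AG and 2AG. With AG alone the Xist ratio was 0.089 and the pan-neuron shift 0.088. The identity call ended with 2AG alone (-0.097) and without genes of the in-slice controls (-0.19). Calls of oligodendrocytes (0.39), the cell cycle (0.59), synapse factors (-0.29) and oxidative phosphorylation (-0.28) ended without the highest cells.

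Cells labelled with Trps1 gRNA at day 21 were set against the same no gRNA cells, so chance in that reference enters both comparisons. The microglial genes Ctss (1614 CPM), C1qc (789 CPM), Cx3cr1 (394 CPM), Lyz2 (564 CPM), Laptm5 (436 CPM), the growth factor receptor Csf1r (514 against 25.5 CPM) and the Fc receptor Fcgr3 (446 against 0.114 CPM) were higher. Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the MHC class II invariant chain, stood at 1420 CPM (1405 to 1434) in 16 of 30 cells and was read in 0 of 23 no gRNA cells, which allows a share of up to 14.8%. H2-D1 (964 CPM) and H2-K1 (664 CPM) were higher with B2m, their shared light chain (1207 against 56.9 CPM), and Ifitm3, an interferon-induced antiviral protein (126 against 4.49 CPM). Lower were Dhcr7 (43.6 CPM), Cwc22 (14.3 CPM), Xist (0.038 CPM), Igfbp2 (97.2 CPM), the adenosine receptor Adora2b (40.6 against 331 CPM), the GABA receptor subunit Gabrg1 (29.97 against 159 CPM), the thyroxine carrier Ttr (8.31 against 113 CPM), and Slc35f6, Zfp949 and Npepl1 (log2 ratios -4.25, -3.18 and -2.41).

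Against no gRNA cells the Trps1 gRNA pool had list shifts of 3.76 for microglia and macrophages (100), 1.87 for reactive astrocytes (100), 1.17 for the cell cycle (100), 1.16 for interferon and antiviral genes (99.99) and 1.14 for endothelium (99.96). Astrocyte identity (-0.56, 0.02), glutamate and ion handling (-0.79, 0), synapse factors (-0.73, 0.09), the circadian clock (-0.80, 0.08), extracellular matrix (-0.54, 1.21), cholesterol synthesis (-0.40, 1.48) and oligodendrocyte progenitor genes (-1.49, 0.10) were lower relative to other genes, whose median log2 ratio was 0.41. Summed identity genes stood at 61742 against 62129 CPM, and the list medians of identity and cholesterol synthesis were -0.075 and 0.038. With title series 21T2 alone the endothelial shift was -1.58 and the identity shift -0.24, inside chance lists, and with 21T3 alone the endothelial shift was -1.17. Without the highest cells the calls of endothelium (0.30), the cell cycle (0.59), the clock (-0.32), extracellular matrix (-0.40) and cholesterol synthesis (-0.36) ended. Progenitor genes summed to 138 against 271 CPM, and to 112 against 115 CPM without the highest cells, and their call ended with AG alone (-0.38). In batch 5, no gRNA replicates 47 and 51 were nearly identical (chi-square per gene 1.72 over 4090 genes, where the next lowest pair of the batch had 28.7). They may be 1 cell counted as 2, and with the pair counted as 1 the cell cycle shift of Sox9 gRNA cells was 0.86 (96.6), inside chance lists.

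At day 7, Sox9 gRNA and dual gRNA cells were set against the 6 no gRNA cells of batch 3, whose totals had a median of 236508 reads. Microglial genes were again higher: C1qb stood at 1733 CPM in Sox9 gRNA cells (20 of 21) and 1161 CPM in dual gRNA cells (14 of 14) and was read in 0 of 6 no gRNA cells. C1qc (1098 and 956 CPM), the lysosomal enzyme Lgmn (1238 and 848 against 0.303 CPM), Ctss (1480 and 1006 against 98.2 CPM) and C1qa (1051 and 836 against 38.2 CPM) followed. Gfap, the intermediate filament of reactive astrocytes, stood at 890 and 749 against 133 CPM, and H2-D1 at 1028 and 524 CPM. Sox9 gRNA cells also held more H2-K1 and Mbp, the myelin basic protein (2281 against 241 CPM), and dual gRNA cells more Clip3, Laptm5 and the matricellular protein Sparc (477 against 0.607 CPM). Lower in both were the zinc and manganese transporter Slc30a10 (33.9 and 4.35 against 283 CPM) and the homeobox gene Pou3f4 (12.3 and 2.9 against 170 CPM). Sox9 gRNA cells held less Dio2, which activates thyroid hormone (57.01 against 328 CPM), and less Aldh9a1, Chadl, Clmn, Mnt, Tlr3, Trmt10c and Zfyve26 (log2 ratios -5.68 to -3.07). Dual gRNA cells held less Eps8 (3.65 against 561 CPM), Adora2b (0 against 599 CPM), the phagocytic receptor Mertk (1.97 against 331 CPM), Tlcd1, Ehmt1, Mtcl1, Nr4a2 and Rbm7 (log2 ratios -5.38 to -3.62).

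The microglia list shifted by 4.30 in Sox9 gRNA and 3.57 in dual gRNA cells (both 100), the reactive list by 1.28 and 2.05 (both 100), the p53 response by 0.72 (98.0) and 1.19 (99.05), oligodendrocytes by 2.38 (100) and 1.09 (99.2), and their progenitors by 2.07 and 2.33 (both 99.98). Cholesterol and fatty acid synthesis shifted by -1.38 (0.29) and -1.90 (0). Over all genes the median log2 ratio was 1.43 and 1.38, and that of the cholesterol list itself -0.30 and -0.72. Interferon genes shifted by 0.71 (99.3) in Sox9 gRNA cells. In dual gRNA cells the cell cycle shifted by 0.96 (99.9), astrocyte identity by -1.20 (0.40) and glutamate and ion handling by -2.06 (0.02), where Sox9 gRNA cells had 0.29 (92.3), -0.11 (42.1) and -0.76 (7.66). Mitochondrial genes took 4.52% of the Sox9 gRNA, 2.40% of the dual gRNA and 1.80% of the no gRNA pool. The difference between the gRNA pools was not tested in that form, and the identity shift of Sox9 gRNA cells lay beyond chance lists without the highest cells (-1.22) and on mean log2 values (-0.84). That of dual gRNA cells lay inside them without genes of the in-slice controls (0.15) and with series 7ST alone (-0.60), where the progenitor shift was -0.14. The oligodendrocyte call of dual gRNA cells ended without the highest cells (1.78, 92.8).

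Dual gRNA cells were then set against Sox9 gRNA cells of day 7 directly, which asks what the added Trps1 gRNA goes with. Serpina3n, a protease inhibitor of reactive astrocytes (1607 against 255 CPM), the protease inhibitor A2m (275 against 34.1 CPM), the channel subunit Cacng4 (163 against 2.23 CPM), Errfi1 (186 against 13.2 CPM) and Rab40b (126 against 2.596 CPM) were higher in dual gRNA cells. Myelin genes were lower, with Mbp at 79.6 against 2281 CPM, Mag at 0 against 228 CPM and Mobp at 20.02 against 213 CPM, as were Cbs, which makes cystathionine (2.81 against 193 CPM), Cyp4f13 (7.95 against 192 CPM) and the glucose transporter Slc2a1 (11.5 against 166 CPM). The cell cycle list shifted by 1.25 (100), with the nucleotide reductase Rrm2 at 283 against 38.2 CPM in 4 of 14 and 3 of 21 cells, neurogenic and neuronal progenitor genes by 1.12 (99.7) and reactive genes by 0.66 (99.5). Oligodendrocyte (-1.50, 0), microglia (-0.54, 1.02), identity (-0.50, 0.08) and glutamate and ion handling lists (-0.76, 0.02) were lower. With series 7ST alone the ratios of Serpina3n and Errfi1 were -1.50 and -1.42 and the shifts of reactive genes -0.37 and of microglia 0.26, all opposite. With series 7S alone the identity shift was -0.25, inside chance lists, as were reactive genes (0.21) and microglia (-0.42) without the highest cells.

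Sox9 gRNA and Trps1 gRNA cells of day 21 were compared within batch 5. Higher in Sox9 gRNA cells were Rasa3, a Ras GTPase activator (262 against 16.9 CPM), Rars, the arginine tRNA synthetase (111 against 11.3 CPM), the nucleoside transporter Slc29a3 (162 against 26.8 CPM), Tmem94 (175 against 12.4 CPM) and Hcfc1 (78.0 against 24.3 CPM). Serpina3n was lower (2.75 against 255 CPM, 2 of 21 against 14 of 30 cells), with Cmtm5 (39.2 against 282 CPM), Mpzl1, Erg28 and the translation factor subunit Eif2b2 (log2 ratios -4.45, -3.73 and -3.81). Oligodendrocyte markers shifted by 1.95 (100), progenitors by 1.83 (99.98) and microglia by 0.70 (99.99). Neuronal markers were lower in every class, by -0.72 for excitatory (1.14), -1.94 for inhibitory (0.01) and -0.76 for pan-neuronal genes (0.04), as were reactive genes (-0.64, 0.40), oxidative phosphorylation (-0.32, 2.39) and endothelium (-1.24, 0.03). With the highest cells left out the calls of oligodendrocytes (0.37) and oxidative phosphorylation (-0.24) ended. The endothelial shift was then 0.33, and 1.96 with series 21T2 alone and 1.97 with 21T3 alone. With series 21T alone Serpina3n had a ratio of 0.42, and reactive genes and oxidative phosphorylation had shifts of 0.36 and 0.11.

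Control gRNA cells of days 21 and 7 were compared in batch 2, which gives the course without a target. MHC class II genes and the chemokine Ccl5 were higher at day 21, with Cd74 at 1841 CPM (7 of 7 cells) against 5.61 CPM (1 of 8), H2-Aa at 871 against 0.055 CPM, H2-Eb1 at 529 against 0.220 CPM, Ccl5 at 946 against 0.110 CPM, and the peroxisomal enzyme Ech1 at 632 against 35.3 CPM. Lower at day 21 were the interferon regulatory factor Irf1 (0 against 876 CPM), the lysosomal glucosidase Gaa (0.201 against 416 CPM), the immediate early gene Nr4a1 (75.3 against 487 CPM), the plasminogen activator Plat (52.96 against 517 CPM) and Tsc22d1 (132 against 693 CPM). Of 25 lists, 9 were lower beyond chance lists. They were target-related transcription factors (-1.37, 0.59), astrocyte identity (-0.77, 0.10), with the water channel Aqp4 at 136 against 639 CPM, reactive genes (-1.11, 0.85), the p53 response (-1.61, 0.57), extracellular matrix (-1.63, 0.89), Notch and related signalling (-1.30, 0.78), immediate early genes (-0.93, 0.40), glycolysis and lactate (-0.84, 2.04) and pericyte genes (-4.65, 0.01, 3 members). Oligodendrocyte progenitor genes shifted by 2.33 (99.8), with a summed level of 736 against 372 CPM that turned to 32.4 against 245 CPM without the highest cells, and the call ended on mean log2 values (1.11). Of its members, Vcan stood at 46.2 against 166 CPM. The glycolysis call ended without the highest cells (-0.52), and the identity call on mean log2 values (-0.68). Mitochondrial genes took 5.998% of the day 21 pool and 3.17% of the day 7 pool. The in-slice control of this batch, labelled day 7, held 5617 CPM of Cd74.

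Across the gRNA groups of batches 2 to 5, Cd74 was read in 12.5% to 28.6% of cells in 4 pools of day 7 and in 47.6% to 100% in 7 pools of day 21. Within batch 4 the shares were 13.3% of Trps1 gRNA cells at day 7 and 81.2% to 100% of the 3 pools at day 21, with 5009 CPM in control gRNA, 2569 in dual gRNA and 1205 in Sox9 gRNA cells. In batch 1, where day was not used, Cd74 was read in 7 of 10 control gRNA and 4 of 4 dual gRNA cells. No gRNA cells held 1 read in 31 cells of batch 1 and none in batches 3 and 5. The days of different batches were not tested against each other. Within batch 4 the gRNA and the sex-linked genes differ between the days as well.

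**Figure D2:**
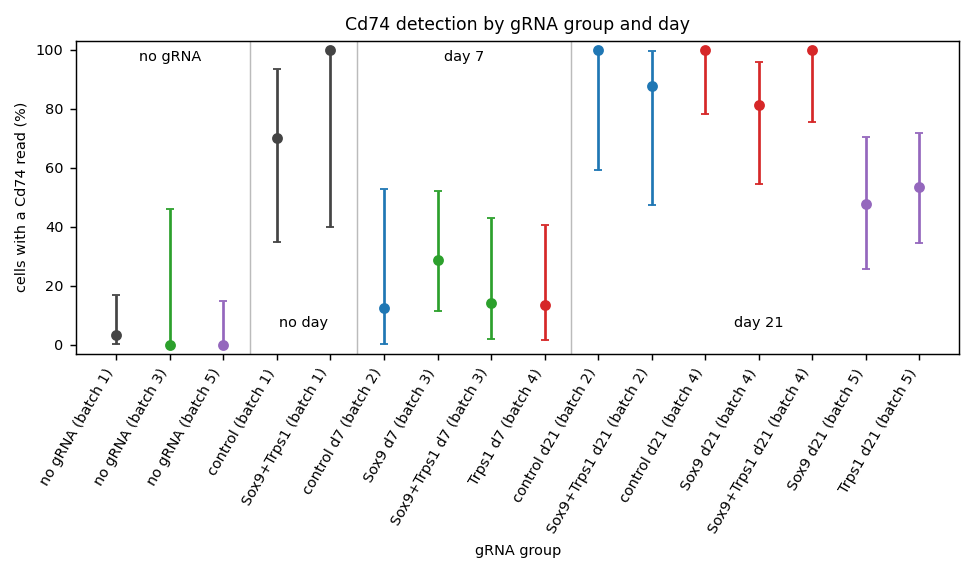
Share of cells with at least 1 Cd74 read (percent), by gRNA group, day and batch. Points are pools, bars are exact 95% binomial intervals for counting error only, and colours mark batches. In batch 1 the gRNA pools have no day. The 7 pools of day 21 lie between 47.6% and 100%, above the 4 pools of day 7 (12.5% to 28.6%), and intervals of some pools overlap.

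Control gRNA cells, whose gRNA targets neither gene, were set against no gRNA cells in batch 1. Animals of the no gRNA cells may not have had the virus or the injection, so these cannot be told apart from the gRNA. Sex-linked genes differed as well. Of control gRNA cells, 5 held 10 or more reads of Xist alone and 0 of Y-linked genes alone, against 8 and 10 no gRNA cells. Higher in control gRNA cells were Gbp2, an interferon-induced GTPase, at 2225 against 0.377 CPM, the chemokine Cxcl10 at 1275 against 3.17 CPM, Ctss at 1601 against 25.2 CPM, Cd74 at 1479 against 0.031 CPM and H2-D1 at 1275 against 6.72 CPM. Lower were Bcan, the astrocyte proteoglycan brevican (10.7 against 1695 CPM), Slc27a1 (0.543 against 892 CPM), the clock gene Per1 (53.1 against 513 CPM), Acsl3 (65.4 against 465 CPM) and Cyp2d22 (57.3 against 367 CPM). The microglia list shifted by 3.89, interferon genes by 3.41, reactive genes by 3.30 and the cell cycle by 2.61 (all 100), and inhibitory neuron markers by 1.48 (98.0). Astrocyte identity shifted by -2.36, glutamate and ion handling by -2.21, Notch and related signalling by -2.14, the circadian clock by -1.91 and cholesterol synthesis by -1.87 (all 0). Target-related transcription factors (-1.48, 0.09), extracellular matrix (-1.06, 1.74) and synapse factors (-0.99, 2.45) were lower too. Mitochondrial genes took 3.13% of the control gRNA pool and 1.50% of the no gRNA pool. Without the highest cells the inhibitory neuron shift was -0.36.

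**Figure D3:**
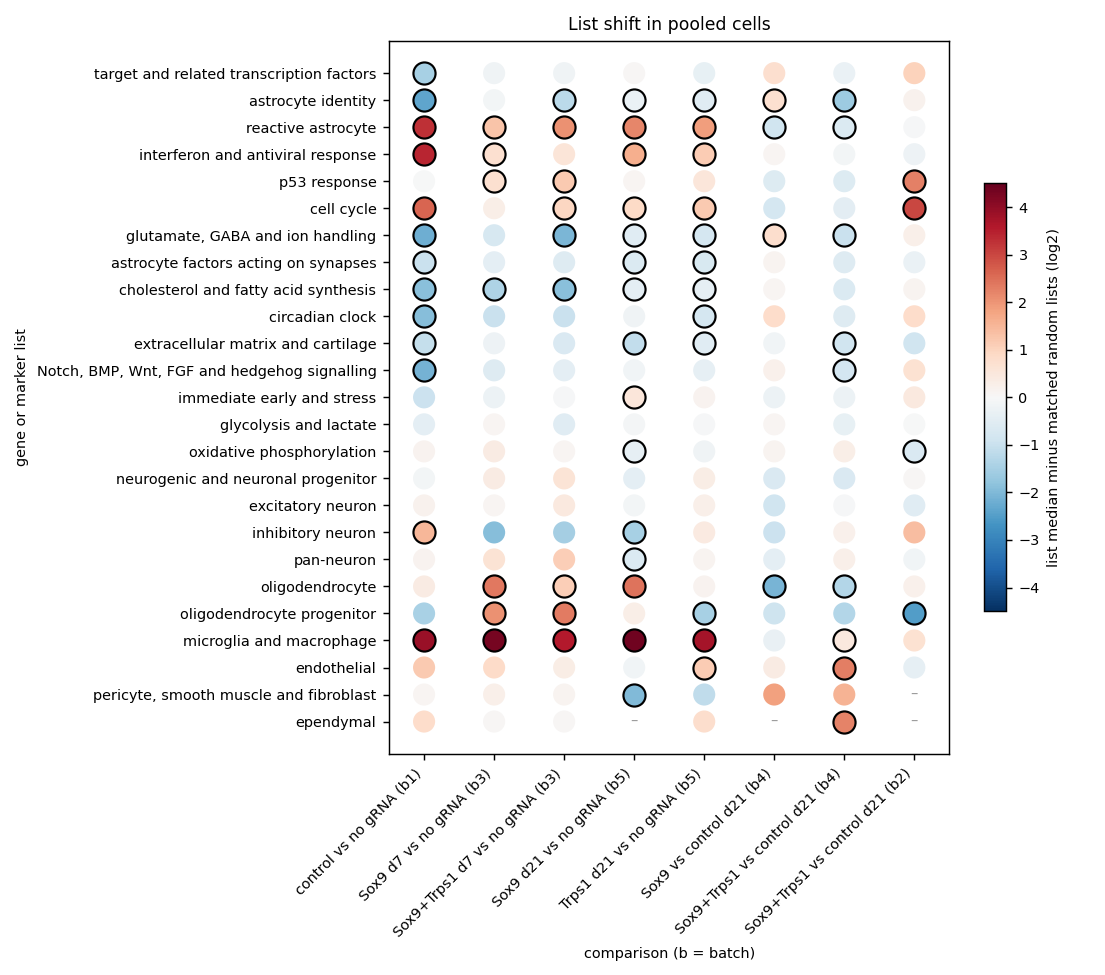
List shift (log2, list median minus matched random lists) by gene or marker list and comparison, with batches as b1 to b5. Red is higher and blue lower in the group named first, a black ring marks a shift beyond the percentile limits of 10000 random lists, and a dash marks too few members. The microglia and macrophage shifts against no gRNA lie between 3.57 and 4.38.

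In-slice controls, which hold RNA the pipette took up without a cell, held microglial and astrocyte transcripts as well. Summed microglial markers reached 33155 CPM in batch 2 (1 library), 32746 in batch 3 (4), 4372 in batch 4 (2) and 6122 in batch 5 (5). The libraries of batch 3 ran from 4.199 to 84005 CPM (median 7363; pool without the highest 4110), and those of batch 5 from 0 to 20755 (median 1336; pool without the highest 3123). No gRNA pools held 317 to 396 CPM and pools with a gRNA 6729 to 15495 CPM. Summed astrocyte identity genes in the in-slice controls stood at 16435, 14711, 2444 and 11431 CPM, and pan-neuronal genes at 1448, 3754, 4566 and 9774 CPM, in the same order of batches. With genes at 20 CPM or more in the in-slice controls left out, the identity shift of dual gRNA against no gRNA cells at day 7 was 0.15.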

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

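Every test of an explanation given here was chosen after the results it bears on had been seen.

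Genes of microglia and macrophages were higher in all 5 gRNA pools set against cells with no gRNA. Targeting by a Sox9 or Trps1 gRNA as the whole cause is argued against by cells of batch 1 labelled with control gRNA, with a list shift of 3.89 over no gRNA cells (percentile 100). These cells held less Trps1 (4.61 against 96.1 CPM) and Sox9 (209 against 524 CPM) than no gRNA cells, so low target transcripts of another origin are not excluded. For RNA carried in by the pipette, the in-slice controls of batch 3 held 2.72 times the summed microglial CPM of the Sox9 gRNA pool (32746 against 12021), but 0.342 times without 1 library at 84005 CPM, and those of batch 5 held 0.509 times (6122 against 12033), or 0.259 times without the highest library, so pipette RNA and RNA inside the taken cells cannot be told apart in either batch. A response to the virus or the injection, which the no gRNA animals may not have had, stays open and was not tested.

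Cd74 was read in a larger share of cells at day 21 than at day 7 in the pools with a day. Other MHC class II genes were compared between the days in batch 2 control gRNA cells alone. In control gRNA cells of batch 2, the microglial list shifted by -0.089 between the days while the median log2 ratio of 4 MHC class II genes was 7.27. That argues against a larger amount of microglial RNA at day 21 in those cells. In batch 4 the microglial list was lower in Trps1 gRNA cells of day 7 than in control gRNA cells of day 21 (-0.78, percentile 0.87). The gRNA and the sex-linked genes differ there as well, so the question stays open in that batch. Targeting by gRNA as the whole cause is argued against by control gRNA cells of batch 4, of which 100% held a Cd74 read (at least 78.2% by the binomial interval). Low target transcripts are not excluded by that pool, which held 3.35 CPM of Trps1. Pipette RNA is argued against in batch 4 by 2 in-slice libraries alone, with a ratio of in-slice to control gRNA Cd74 of 0.00125 (6.27 against 5009 CPM, and 0.00114 without the higher library). In-slice libraries of other batches differed widely in microglial RNA, so 2 libraries do not exclude it. In batch 2 the ratio was 3.05 (5617 against 1841 CPM) from a single library labelled day 7, and in batch 5, against Sox9 gRNA cells, 0.402 (134 against 334 CPM; 0.271 without the highest library), so pipette and cell RNA cannot be told apart there, and a time course of the response to injection is a hypothesis that these pools do not test.

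Cwc22 and Xist were both higher in no gRNA than in gRNA cells of batch 5. For Xist the sex of the animals is a candidate explanation, since title series 2AG held 346 CPM in 12 of 12 cells and series AG 0.251 CPM in 1 of 11. The Y-linked gene Ddx3y went the other way, at 0.207 CPM in 2AG (2 of 12 cells) and 93.9 CPM in AG (7 of 11). Sex is argued against for Cwc22, which was read in 90.9% of AG cells (58.7% to 99.8%). Another mouse line for the no gRNA cells of all batches would need Cwc22 in every batch. In batch 3 it was read in 16.7% of 6 cells (0.421% to 64.1%), too few cells to decide. Batch 3 has no bearing on a line used for batch 5 alone. Within batch 5, Cwc22 stood at 330 CPM in series AG (10 of 11 cells) and 284 CPM in 2AG (11 of 12). As these series differ in sex-linked genes, that argues against 1 animal as the source. A line difference and one between small sets of animals cannot be told apart. GFP in batch 5 stood at 147 CPM in no gRNA, 64.0 CPM in Sox9 gRNA and 82.9 CPM in Trps1 gRNA cells, which was not tested against a line.

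In 7 of 47 small groups and measures 1 cell stood far from the rest. Chance gives about 1 in 20 for normally distributed values, which CPM per cell are not, so no excess is claimed. Dual gRNA replicate 4 of batch 2 held 7131 genes, with the next cell at 3914, and 116.9 CPM of Trps1, with the next at 0.798. Control gRNA replicate 9 of batch 1 had 11.3% mitochondrial reads, with the next at 5.51%. Trps1 stood at 786 CPM in dual gRNA replicate 2 of batch 1 (next 91.9) and at 272 CPM in no gRNA replicate 33 of batch 3 (next 62.7). In-slice controls gave Sox9 at 0.463 CPM in replicate 4 of batch 3 and Trps1 at 1.73 CPM in replicate 12 of batch 5, which are 1 and 2 reads. All others there held 0, so any library with a read stands apart by construction.

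Dual against control gRNA at day 21 gave opposite signs in batches 4 and 2, a difference that was not tested. The pairs, batch 4 first, were -0.41 and 0.88 for Sox9, and 1.38 and -2.20 for Trps1. Among lists they were -1.64 and 0.19 for astrocyte identity, -0.62 and 2.28 for the p53 response, -0.48 and 2.99 for the cell cycle, and -0.996 and 0.26 for glutamate and ion handling. They were -0.84 and 0.68 for Notch and related signalling, 0.29 and -0.68 for oxidative phosphorylation, -1.31 and 0.22 for oligodendrocytes, and 2.31 and -0.40 for endothelium.

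Guide, reporter and vector sequences stood outside the gene comparisons. In batch 3 the in-slice controls held 1 read of each Sox9 guide, where no gRNA cells held 0. Sox9 gRNA cells held 5 reads of the Trps1 guide in 4 of 21 cells, where no gRNA cells held 0 as well. In batch 4, GFP reads numbered 49 in the in-slice controls (30.7 CPM), 1327 in Sox9 gRNA cells (75.9 CPM) and 892 in Trps1 gRNA cells (46.1 CPM), above the 21.8 CPM of control gRNA cells, and Trps1 gRNA cells held 4 reads of the Lmo4 overexpression sequence (0.207 CPM), against 3 reads in control gRNA cells (0.165 CPM). DsRed in batch 4 was highest in control gRNA cells, at 8330 CPM. It stood at 4263 CPM in Sox9 gRNA, 1554 CPM in dual gRNA and 1229 CPM in Trps1 gRNA cells. The in-slice controls there held 424 CPM. In batch 5, DsRed reads numbered 503 in the in-slice controls, 67285 in Sox9 gRNA cells (3939 CPM) and 15230 in Trps1 gRNA cells (576 CPM). No gRNA cells held 0.397 CPM. The Lmo4 overexpression sequence had 6 reads in Sox9 gRNA (0.351 CPM) and 19 in Trps1 gRNA cells (0.718 CPM) of that batch, against 5 reads in no gRNA cells (0.284 CPM).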

How the results depend on the processing

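All settings were chosen before the data were examined unless named as added. No paired analysis was possible because the running numbers of cells pair nothing across groups, each group is 1 pool and no test was made. Of 3474 list values, 3093 counted as the same. There a called list kept its call and direction, or an uncalled list stayed uncalled, whatever its sign. They include 248 values with TMM factors, which cannot move a list shift. Of the rest, 189 lost a call, 161 gained one in the same direction and 10 in the other, and 21 called lists reversed. Of 2056 gene ratios, 709 stayed within the counting error, 1322 moved and 25 reversed. That error leaves out the spread between cells, so most gene ratios move with the setting. The cause of each change below was not tested, except that a title series decides where it alone was kept. The highest cell was picked for each gene on its own, so a list without the highest cells drops different cells for its members. A list call that ended that way need not rest on 1 cell. Depth limits the 6 no gRNA cells of batch 3 most, of which 3 were too shallow for thinning. Each replicate left out in turn was not run, as the labels do not assign cells to animals. Comparisons with Trps1 gRNA cells of day 21 in batch 4 could not be made.

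In the following, S/C is Sox9 against control gRNA and D/C dual against control gRNA (batch 4), S/N and T/N are Sox9 and Trps1 against no gRNA at day 21, S/T is Sox9 against Trps1 gRNA (batch 5), s/n, d/n and d/s are the same at day 7, with d for dual (batch 3), and C21/C7 is control gRNA by day (batch 2).

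With every cell weighted alike, Sox9 was 0.49 (S/C), -0.51 (S/N), 2.1 (s/n), 2.1 (d/n) and, reversed, -0.015 (d/s). Trps1 was then 0.20 (D/C), -0.49 (T/N), 0.38 (s/n, reversed) and 2.35 (d/n).

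As a difference of mean log2(CPM + 1), Sox9 was 2.36 (S/C), -1.59 (D/C), -1.16 (S/N), 0.41 (s/n), and reversed at -0.11 (d/n), -0.52 (d/s) and -1.57 (C21/C7). On that scale Trps1 was 0.086 (D/C), -1.51 (T/N), 0.11 (s/n, reversed), 1.2 (d/n) and 1.09 (d/s). The identity list was 0.46 (S/T) and -0.84 (s/n), where a call was gained, and -0.68 (C21/C7), where the call was lost.

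Without the highest cells, Sox9 was 0.40 (S/C), -2.21 (D/C), 0.30 (d/n) and -1.40 (d/s, reversed). Trps1 was 0.071 (D/C), -1.19 (T/N), 2.1 (s/n, reversed), 2.82 (d/n) and 0.71 (d/s). Reversed lists were oligodendrocyte 0.060 (D/C), endothelial 0.33 (S/T) and inhibitory neuron -0.36 (control against no gRNA, batch 1), and identity was -1.22 (s/n).

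TMM factors gave Sox9 at 0.73 (S/C), -0.044 (D/C), 0.92 (s/n) and 1.19 (d/n), and Trps1 at 1.74 (D/C), -0.99 (T/N) and 0.64 (d/n). They moved all ratios of a comparison by up to 0.64 up (S/C) and -0.84 down (s/n). As 1 offset for every gene of a comparison, they cannot move a list shift.

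Thinned to 1 depth, cells gave Sox9 at 0.65 (S/C), -0.26 (D/C), 1.62 (s/n) and 1.49 (d/n), and Trps1 at 0.42 (D/C) and -0.49 (T/N).

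A prior of 1 CPM gave Trps1 at 2.03 (D/C), and 20 CPM gave 0.65 (D/C) and 1.74 (d/s).

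Lists without genes of the in-slice controls gave identity at 0.64 (S/C), -0.19 (S/N), where the calls ended, and 0.15 (d/n, reversed).

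Batch 2 for batch 4 reversed D/C for Sox9 (0.88), Trps1 (-2.20) and the lists of identity (0.19), glutamate and ion handling (0.26), Notch and related signalling (0.68), oligodendrocytes (0.21) and endothelium (-0.40).

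Series 21S alone (S/C) reversed Alas2 (-0.078), Col1a1 (-0.51), Hbb-bs (-1.19), Spp1 (-0.11), identity (-0.13) and glutamate and ion handling (-0.15), with Sox9 at 0.32. Series 21S2 alone gave Sox9 at -0.064.

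Series AG alone reversed Xist (0.089) and pan-neuron genes (0.088) in S/N, with Sox9 at -0.15 and Trps1 at -1.43 (T/N). Series 2AG alone gave Sox9 at -0.57 and identity at -0.10 (S/N), and reversed Trps1, at 0.26 (S/N) and 0.75 (T/N).

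Series 21T alone gave Trps1 at -1.06 (T/N) and reversed Serpina3n (0.42), reactive genes (0.36) and oxidative phosphorylation (0.11) in S/T. Series 21T2 alone reversed Trps1 (0.41) and endothelium (-1.58) in T/N and endothelium in S/T (1.96), with identity at -0.24 (T/N). Series 21T3 alone gave Trps1 at -2.77 (T/N) and 1.66 (S/T, reversed), endothelium, reversed, at -1.17 (T/N) and 1.97 (S/T), and identity at 0.61 (S/T).

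Series 7S alone gave Sox9 at 0.11 (s/n), Trps1 at 3.13 and identity at -0.25 (d/s). Series 7S2 alone gave Sox9 at 2.84 (s/n) and -0.89 (d/s, reversed), and Trps1 at 0.42 (s/n, reversed) and 0.97 (d/s).

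Series 7ST alone gave Sox9 at 0.12 (d/n) and -1.64 (d/s, reversed), Trps1 at 0.038 (d/n) and 0.56 (d/s), and identity at -0.60 (d/n). It reversed progenitors (-0.14, d/n) and, in d/s, Errfi1 (-1.42), Serpina3n (-1.50), reactive genes (-0.37) and microglia (0.26). Series 7ST2 alone gave Sox9 at 2.66 (d/n) and Trps1 at 2.02 (d/n) and 2.54 (d/s).

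Counting the near-identical pair of batch 5 as 1 cell, an alternative added after seeing the data, left 40 of 44 gene ratios and 47 of 49 list values the same and reversed none. It ended the cell cycle call of S/N (0.86) and gave a Notch signalling call in T/N (-0.45). Leaving out the highest cells of batch 2, also added, ended the calls of dual against control gRNA there for the cell cycle (-0.040), the p53 response (1.02) and oxidative phosphorylation (-0.46), and gave calls for immediate early genes (0.72) and microglia (0.88). Leaving out mitochondrial genes, also added, kept 247 of 248 list values.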

Other observations

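The comparison of Trps1 gRNA and control gRNA cells, with and without its near-identical cells counted as 1, and the check for near-identical cells below were chosen after the data had been seen.

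Trps1 gRNA cells of batch 4 had columns at day 7 alone, and the control gRNA cells of that batch are of day 21, so gRNA and day differ together. In the Trps1 gRNA pool, genes of the p53 response (shift 1.403, percentile 99.9) and of the cell cycle (1.61, 99.98) were higher, as were markers of pericytes, smooth muscle and fibroblasts (2.08, 99.5) on 4 members. Astrocyte identity genes (-1.08, 0.01), cholesterol and fatty acid synthesis (-0.98, 0.89), extracellular matrix genes (-0.75, 2.29), oligodendrocyte markers (-3.14, 0) and microglial markers (-0.78, 0.87) were lower. Mitochondrial genes took 6.83% of the Trps1 gRNA pool and 3.05% of the control pool. This pool holds the near-identical cells 13 and 14 described below. With them counted as 1 cell, every one of these calls stood: 1.49 for the p53 response, 1.39 for the cell cycle, 2.27 for pericytes and related cells, -1.03 for identity, -0.98 for cholesterol synthesis, -0.86 for extracellular matrix, -3.03 for oligodendrocytes and -0.89 for microglia. No other alternative, such as leaving out the highest cells, was run for this comparison. For dual gRNA against the same control cells, the oligodendrocyte shift was 0.060 without the highest cells.

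Cells were sorted by 10 or more reads of Xist and 10 or more reads of 4 Y-linked genes together, a threshold not fixed before the data were seen. None of the 242 astrocytes reached both, while 14 held at least 1 read of each. In batch 5, 16 of 21 Sox9 gRNA and 23 of 30 Trps1 gRNA cells reached the Y-linked threshold without that of Xist, while the no gRNA cells split into 10 with Xist alone, 8 with Y-linked genes alone and 5 with neither. In batch 4 control, Sox9 and dual gRNA cells held Xist alone in 7, 6 and 4 cells and Y-linked genes in none, and Trps1 gRNA cells of day 7 held Y-linked genes alone in 4 cells. By any read, the no gRNA cells of batch 5 split into 10 with Xist alone, 9 with Y-linked reads alone, 3 with both and 1 with neither. Groups compared within batches thus differed in how many cells reached the thresholds.

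Trps1 gRNA cells 13 and 14 of batch 4 had a chi-square per gene of 3.23 over 1674 genes, where the next lowest pair of that batch had 54.1 and the median pair 298. Their totals were 2521554 and 2452180 reads, and their Spearman correlation across genes was 0.73. Cells 47 and 51 of the no gRNA group in batch 5 held 801991 and 923518 reads, with a correlation of 0.91. Both pairs differed by more than sampling noise alone gives. Without molecular identifiers that does not separate 2 cells from 1 cell amplified or sequenced more than once, and each pair was kept as 2 cells in the values above unless counted as 1.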
